A study of Mus musculus with 12 samples.

How the data were processed

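RNA was measured in Tregs in 12 libraries, 4 groups of 3 mice per the series' design text: WT or Treg-specific Tkt knockout (cKO), each given vehicle or DMαKG. Groups and replicate numbers were taken from the sample labels, which number both vehicle groups 2 to 4 and both DMαKG groups 1 to 3. Both genotypes carried the Foxp3-linked Cre per the labels. RNA was extracted with Trizol and sequenced on an Illumina instrument, per the labels' protocols, and the series' design text names the NEBNext Ultra RNA kit for the libraries. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.16.1 and the mm10 build, with no role or order. Whether the counting used strand is not given in the sources used here, so named genes that overlap another gene of the table are reported as uncertain.

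The authors deposited a single table of 17955 genes with estimated read counts, FPKM and TPM for each library. The deposited estimated counts are not normalized, and 36.0% of their values were not whole numbers, so they were rounded before any count test; the tests had been planned for whole-number counts. The FPKM values that the authors deposited are scaled by transcript length and library size, and the TPM values that the authors deposited are scaled to the same sum in each library, per the file headers; neither was used in a test. Summed estimated counts per library ran from 1.57e+07 to 1.89e+07, and 153 genes were at 0 in every library. The table pairs gene IDs with symbols, and 17901 IDs matched a RefSeq gene table of the GRCm38.p6 assembly, the same build as mm10, from which coordinates were taken; 17781 were protein coding. Of the 13 mitochondrially encoded genes 0 were in the table.

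Changes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter, which left 12903, libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, with 8 residual degrees of freedom. The common biological coefficient of variation was 19.7%. The contrasts were cKO against WT within each treatment, DMαKG against vehicle within each genotype, and their interaction. P-values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05. CPM values use the TMM-scaled library sizes, and errors are SDs over 3 mice.

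Of 44 gene lists covering metabolism, Treg function, T helper programmes, stress responses, proliferation and markers of other cell types, 39 had at least 5 tested members. They were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, again with a correlation estimated for each list, and with fry, whose directional test asks whether members move on balance 1 way. Adjusted p-values of lists are over the 39 lists of a contrast. The lists, groups, tests, settings to vary and naming rule were fixed before the data were examined.

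Genes were named by a rule. Tkt comes first in every library, then Foxp3, Il2ra, Ctla4, Ikzf2, Il10 and Tnfrsf18. Each pairwise comparison gives up to 10 protein-coding genes per direction with the largest change among those past the threshold, with a mean of at least 5 CPM in a group and no overlap between the groups' libraries, or, where none passed, the 3 with the smallest unadjusted p. The interaction gives the 5 with the smallest p per direction, or 3 in all where none passed. Each list gives the up to 4 members past the threshold with the smallest p, or, where none passed, at most 2 members as values. Sex-linked genes were read as a check of the mice. Immunoglobulin and T cell receptor variable segments are not named, and some genes that the rule names are not reported here.

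The alternatives were DESeq2 size factors or upper-quartile scaling, no low-count filter or at least 1 CPM in 6 libraries, DESeq2 1.42.0 with its Wald test, limma voom with sample quality weights, a fit on only the groups compared, the replicate number as a block, an absolute log2 fold change of at least 1, an adjusted p below 0.01, and leaving out each library in turn. The block was the number within each treatment for the genotype contrasts and the interaction, and the number alone for the DMαKG contrasts. Chosen after seeing the data were a covariate of Y-linked expression (mean log2 CPM of Ddx3y, Kdm5d and Eif2s3y), removal of each library's trend on transcript length and GC content, leaving out 3 libraries that lay together on the first principal component, and comparisons averaged over the other factor. The fits were tested on simulated data drawn from the real means for cKO against WT with vehicle, over 12770 genes. In these 200 were changed, all with a mean of at least 5 CPM, so the shares do not cover genes with lower counts. The run made 153 calls, so its adjusted threshold lay at a larger unadjusted p than in the real comparison, where 8 genes passed. The share recovered was 22.0% of 50 genes changed 1.5-fold, 76.0% at 2-fold, 90.0% at 3-fold and 98.0% at 4-fold, and 10 of 153 calls were unchanged genes. No pair of libraries agreed within counting noise: the lowest chi-square per degree of freedom between libraries was 10.2.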

Results

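RNA was sequenced from regulatory T cells (Tregs) sorted as CD4+CD25+YFP+ cells from the spleen and lymph nodes of 7-week-old C57BL/6 mice. The mice were wild type (WT) or lacked the transketolase gene Tkt in Tregs (cKO), deleted by a Cre recombinase that is expressed with a yellow fluorescent protein from the Foxp3 locus. Transketolase is an enzyme of the non-oxidative pentose phosphate pathway. Mice of both genotypes drank water with vehicle or with DMαKG, dimethyl α-ketoglutarate, a cell-permeable ester of α-ketoglutarate, from pregnancy until adulthood. This gave 4 groups of 3 mice and 12 libraries, and all p-values below rest on 3 mice per group. The summed estimated count per library ran from 1.57e+07 to 1.89e+07, and 12333 to 12608 genes per library had a count of at least 10. Of 17955 genes in the deposited table, 12903 had enough counts to be tested. At these depths the median standard error of a log2 fold change between groups was 0.18.

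Tkt (gene 21881, chromosome 14, 30549131 to 30574724, GRCm38) was low in every cKO library. With vehicle it stood at 133, 102 and 111 CPM (counts scaled to the TMM-adjusted library size) in WT replicates 2, 3 and 4, and at 26.2, 37.2 and 41.8 CPM in cKO replicates 2, 3 and 4. With DMαKG it stood at 110, 137 and 194 CPM in WT replicates 1, 2 and 3, and at 37.8, 34.6 and 31.5 CPM in cKO replicates 1, 2 and 3. The cKO mean was 30.4% of the WT mean with vehicle and 23.6% with DMαKG, with log2 fold changes of -1.72 (SE 0.21, edgeR adjusted p = 0.0148) and -2.08 (SE 0.22, adjusted p = 0.00389). Leaving out cKO vehicle replicate 2 or 3 raised the adjusted p with vehicle to 0.0865 and 0.0505. In a fit on only the groups compared it was 0.0803, with a log2 fold change of -1.72. With the replicate number as a block the edgeR adjusted p was 0.213 with vehicle and 0.196 with DMαKG, at log2 fold changes of -1.73 and -2.05.

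**Figure D1:**
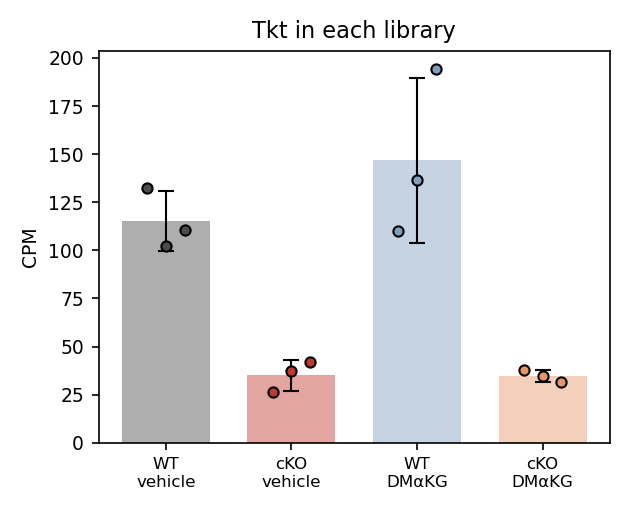
Tkt in CPM (vertical axis) in the 4 groups. Points are libraries, bars are group means and error bars are SDs (n = 3); the cKO libraries lie between 26.2 and 41.8 CPM and the WT libraries between 102 and 194 CPM.

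The libraries also differed in Y-linked transcripts, which the group labels do not describe. Ddx3y, a Y-linked helicase gene, stood at 0.0555, 0.518 and 0.509 CPM in WT vehicle replicate 3, cKO DMαKG replicate 1 and cKO DMαKG replicate 3. It stood at 22.6 CPM in WT DMαKG replicate 2, between the low and the high libraries, and at 109 to 241 CPM in the other libraries. The 3 cKO vehicle libraries thus all had high Y-linked counts (156, 219 and 190 CPM of Ddx3y), and 1 of the 3 cKO DMαKG libraries did. The first and second principal components held 29.0% and 15.4% of the variance. WT vehicle replicate 4, cKO vehicle replicate 4 and WT DMαKG replicate 3 lay together at one end of the first component, at -32.9, -32.8 and -29.7, and cKO DMαKG replicate 3 lay at the other, at 47.0.

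**Figure D2:**
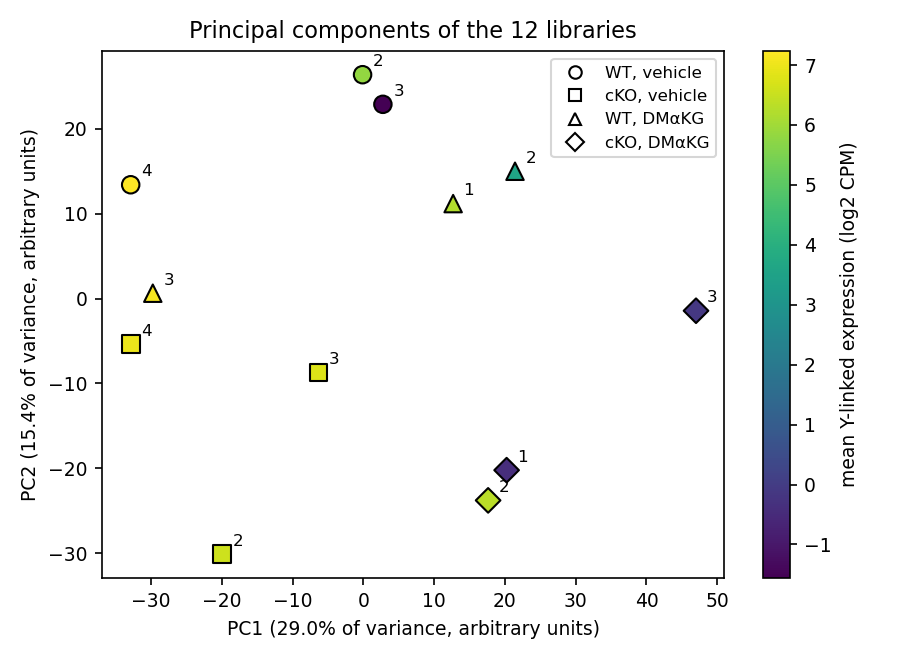
First and second principal components of the log2 CPM values of the 12 libraries (arbitrary units, share of variance on each axis). Marker shapes are groups, numbers are replicates, and colour is the mean log2 CPM of 3 Y-linked genes; WT DMαKG replicate 3 lies at -29.7 on the first component, close to WT vehicle replicate 4 at -32.9.

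The first comparison asked what the loss of transketolase changed in Tregs of mice given vehicle. Ncf1, which encodes a cytosolic subunit of the phagocyte NADPH oxidase, was the gene with the smallest p. It rose from 20.4 ± 3.68 CPM in WT to 56.3 ± 5.87 CPM in cKO (SD, n = 3; log2 fold change 1.47, SE 0.14, adjusted p = 0.00182). Phlda3, a p53 target, and Ncoa7, a member of the nuclear receptor coactivator family, also rose. Nrn1, which encodes neuritin, fell from 34.2 ± 6.09 to 13.5 ± 0.74 CPM, and Cxcr6, the receptor of the chemokine CXCL16, fell from 16.3 ± 4.61 to 4.85 ± 1.5 CPM. Cc2d2a, a gene of the ciliary transition zone, and 5830411N06Rik fell too.

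Together with Tkt these were the 8 genes that passed in cKO against WT with vehicle, 3 higher and 5 lower. The log2 fold change was 1.39 (adjusted p = 0.0455) for Phlda3, 0.64 (0.0455) for Ncoa7, -1.34 (0.0199) for Nrn1, -1.74 (0.0455) for Cxcr6, -1.98 (0.0455) for Cc2d2a and -2.36 (0.0455) for 5830411N06Rik. Ncf1 lies on chromosome 5 (134220053 to 134229628), Phlda3 on chromosome 1 (135766085 to 135769134), Nrn1 on chromosome 13 (36725622 to 36734477) and Cxcr6 on chromosome 9 (123806477 to 123811754). Cxcr6 overlaps Fyco1, so reads of these genes may not be separable without strand information, which the sources used here do not give for the counting. Foxp3, the lineage transcription factor of Tregs, which overlaps Ccdc22, had a log2 fold change of 0.07 (SE 0.20), Il2ra of 0.23, Ctla4 of -0.11 and Ikzf2 of -0.17, and none of these passed. Il10 stood at 25.3 CPM in WT and 9.02 CPM in cKO (log2 fold change -1.49, adjusted p = 0.603) and Tnfrsf18 at 173 and 223 CPM (0.37, adjusted p = 0.648), and neither passed. At an unadjusted p under 0.05 there were 941 genes, 7.29% of those tested, where a share of 0.05 is expected with no change. Of tested genes 15.3% had non-overlapping groups, where chance gives 10%. DESeq2's Wald test called 100 genes and limma voom with sample quality weights 263.

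Among the gene lists fixed beforehand, effector Treg genes fell in cKO with vehicle: 19 of 26 members had a lower and 7 a higher level, with a median log2 fold change of -0.46 (camera adjusted p = 1.95e-06, adjusted p = 0.305 with an estimated correlation). Adjusted over the list alone, 5 members were lower and 0 higher; over all genes 0 passed. Ccr2, a chemokine receptor, stood at 68.0 CPM in WT and 15.4 CPM in cKO (log2 fold change -2.14, adjusted p = 0.118), and S100a4, a calcium-binding protein gene, at 48.2 and 16.1 CPM (-1.58, adjusted p = 0.157). Cytokine and chemokine receptors and homing genes fell as a list as well, with 17 of 26 members lower and a median of -0.20 (adjusted p = 2.57e-05, adjusted p = 0.098 with an estimated correlation); Cxcr6 passed over all genes, and 8 members were lower adjusted over the list alone. This list was the one that also passed fry's directional test in any comparison (adjusted p = 0.0225). Th1, Th2 and Th17 genes had medians of -0.49, -0.48 and -0.34 (adjusted p = 0.0206, 0.00502 and 0.0251, and 0.399, 0.399 and 0.305 with an estimated correlation). Adjusted over the list alone, 4 Th1 genes and 3 Th2 genes were lower, among the latter Il1rl1, the receptor of interleukin-33 (log2 fold change -0.83). Without cKO vehicle replicate 4 these 3 lists had medians of -0.39, -0.78 and -0.31 (adjusted p = 0.429, 0.0629 and 0.0975), so the Th2 call ended with a larger median. Th1 genes also lost their call without WT vehicle replicate 4 (median -0.33, adjusted p = 0.0846), and Th17 genes without WT vehicle replicate 3 (-0.26 and 0.069).

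Markers of other cell types moved in the same libraries. Markers of macrophages and monocytes fell, 18 of 19 being lower with a median of -1.06 (adjusted p = 3.07e-05, adjusted p = 0.584 with an estimated correlation), and so did markers of dendritic cells, 12 of 15 being lower with a median of -0.76 (adjusted p = 2.57e-05, adjusted p = 0.399 with an estimated correlation). Siglech, a marker of plasmacytoid dendritic cells, stood at 11.2 CPM in WT and 1.39 CPM in cKO, and Xcr1, a marker of conventional dendritic cells, at 2.04 and 0.66 CPM; neither passed over all genes, and 4 dendritic cell markers were lower adjusted over the list alone. Markers of erythroid cells had a median of -0.68 (adjusted p = 0.00839, adjusted p = 0.399 with an estimated correlation), lost without WT vehicle replicate 2 (0.0594) or cKO vehicle replicate 2 (0.362).

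Genes of mitosis fell, with 37 of 40 members lower and a median of -0.31 (adjusted p = 1.95e-06, adjusted p = 0.722 with an estimated correlation), and so did genes of DNA replication and S phase, with 35 of 40 lower and a median of -0.16 (adjusted p = 0.00026 and 0.722). No member of either list passed over all genes or over the list alone; Hmmr, a mitotic spindle gene, had a log2 fold change of -0.42. Both falls rested on cKO vehicle replicate 2: without it the medians were 0.02 (adjusted p = 0.498) and 0.08 (adjusted p = 0.618).

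Of the metabolic lists, glycolysis, oxidative phosphorylation and fatty acid oxidation were higher in cKO with vehicle by small amounts. Genes of the pentose phosphate pathway (adjusted p = 0.752), the tricarboxylic acid cycle (0.149), glutamine and glutamate metabolism (0.428), serine and one-carbon metabolism (0.265), fatty acid synthesis (0.471) and cholesterol synthesis (0.38) did not pass as lists. Glycolysis genes rose, with 21 of 24 members higher and a median of 0.16 (adjusted p = 0.000452, adjusted p = 0.305 with an estimated correlation), and 2 passed adjusted over the list alone: Eno2, the neuronal enolase (log2 fold change 1.12, adjusted p = 0.14 over all genes), and Ldhb, a subunit of lactate dehydrogenase (0.57, adjusted p = 0.264). Nuclear genes of oxidative phosphorylation rose, with 69 of 72 members higher and a median of 0.16 (adjusted p = 3.07e-05, adjusted p = 0.722 with an estimated correlation), as did cytosolic ribosomal protein genes, with 79 of 82 higher and a median of 0.16 (adjusted p = 2.57e-05 and 0.722). Without cKO vehicle replicate 4 their medians were -0.01 (adjusted p = 0.744) and 0.06 (adjusted p = 0.259). MYC targets and ribosome biogenesis genes (median 0.13, adjusted p = 0.00031, and 0.463 with an estimated correlation), fatty acid oxidation genes (0.09, adjusted p = 0.0251 and 0.584) and p53 targets (0.12, adjusted p = 0.00502 and 0.305) were higher as lists too and were likewise lost without cKO vehicle replicate 4 (0.0572, 0.57 and 0.0975). The fatty acid oxidation call also ended without WT vehicle replicate 2 (median 0.09, adjusted p = 0.0789) or 3 (0.04 and 0.248). The Treg core signature was higher, with 20 of 28 members up and a median of 0.13 (adjusted p = 0.00421, adjusted p = 0.305 with an estimated correlation); adjusted over the list alone, Plagl1, an imprinted zinc finger gene (log2 fold change 0.69), and Ecm1, an extracellular matrix gene (1.06), were higher.

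Of 39 lists tested, 17 passed camera's test with the preset correlation in this comparison, 7 higher and 10 lower, and 0 with an estimated correlation. Calls also ended with voom quality weights for Th1 (median -0.23, adjusted p = 0.412), Th2 (-0.38 and 0.158), Th17 (-0.44 and 0.111) and fatty acid oxidation genes (0.07 and 0.117), and without a low-count filter for erythroid markers (-0.54 and 0.0562). Leaving out the 3 libraries that lay together on the first component, chosen after seeing the data, ended those of Th1 (median -0.10, adjusted p = 0.732), Th2 (-0.44 and 0.0715), Th17 (-0.45 and 0.0697), oxidative phosphorylation (0.019 and 0.504), fatty acid oxidation (0.027 and 0.205), p53 (0.062 and 0.294), MYC (0.055 and 0.419) and ribosomal genes (0.0027 and 0.732). Removing the length and GC trend, also chosen after, ended that of fatty acid oxidation (0.052 and 0.0567). The gene count depended on every library. It was 5 without WT vehicle replicate 2, cKO vehicle replicate 4, WT DMαKG replicate 3 or cKO DMαKG replicate 1, and 4 without WT DMαKG replicate 1, cKO DMαKG replicate 2 or cKO DMαKG replicate 3. It was 3 without WT vehicle replicate 4 or WT DMαKG replicate 2, 2 without WT vehicle replicate 3, and 1 without cKO vehicle replicate 2 or 3. Ncf1 passed without each of the 6 libraries compared. Fitted on those 6 libraries alone, 0 genes passed, with an adjusted p of 0.0803 for Ncf1 and 1109 genes at an unadjusted p under 0.05. With the replicate number as a block 1 gene passed. With the Y-linked level as a covariate 3 genes passed, and without the 3 libraries that lay together at one end of the first component (WT vehicle replicate 4, cKO vehicle replicate 4 and WT DMαKG replicate 3) 3 genes passed; both alternatives were chosen after seeing the data.

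**Figure D3:**
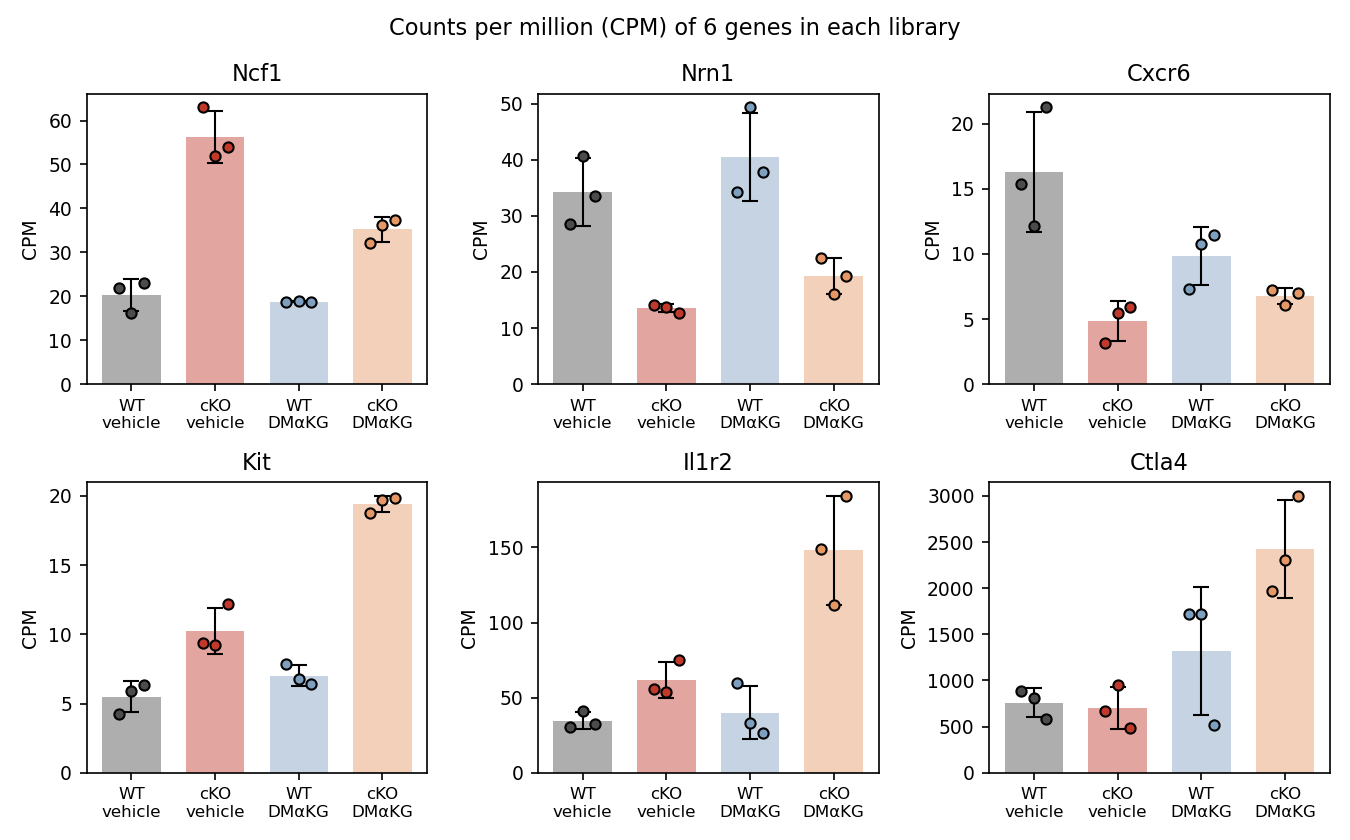
CPM (vertical axis) of Ncf1, Nrn1, Cxcr6, Kit, Il1r2 and Ctla4 in the 4 groups. Points are libraries, bars are group means and error bars are SDs (n = 3); Ncf1 stands at 56.3 CPM in cKO with vehicle against 20.4 CPM in WT, and Ctla4 in WT DMαKG replicate 3 stands at 514 CPM, below the other 2 libraries of its group at 1722 CPM.

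The second comparison asked what DMαKG changed in WT Tregs. Ribosomal protein genes and Treg core signature genes rose as lists, and interferon-stimulated genes fell, all by small amounts and with no single gene passing. Of the ribosomal protein genes 80 of 82 were higher, with a median log2 fold change of 0.20 (camera adjusted p = 1.02e-11, adjusted p = 0.816 with an estimated correlation). Of the Treg core signature 27 of 28 members were higher, with a median of 0.21 (adjusted p = 7.89e-07, adjusted p = 0.0819 with an estimated correlation); Tnfrsf4, which encodes the costimulatory receptor OX40 and is uncertain because it overlaps Sdf4, stood at 173 CPM with vehicle and 249 CPM with DMαKG (log2 fold change 0.52, adjusted p = 0.999), and Izumo1r, the folate receptor 4 gene, at 523 and 630 CPM (0.27, adjusted p = 0.999). Of the interferon-stimulated genes 37 of 40 were lower, with a median of -0.21 (adjusted p = 0.000639, adjusted p = 0.816 with an estimated correlation); Stat2, a transcription factor of interferon signalling that overlaps Apof and is uncertain, had a log2 fold change of -0.35 and Oas2, an oligoadenylate synthetase, of -0.69. The call of the interferon-stimulated list ended without WT vehicle replicate 4 (median 0.01, adjusted p = 0.969), WT DMαKG replicate 1 (-0.12 and 0.0832) or WT DMαKG replicate 2 (-0.10 and 0.127). It also ended with the replicate number as a block (-0.047 and 0.406). Adjusted over the list alone, 0 members of any of these 3 lists passed.

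In the same WT libraries, markers of dendritic cells were lower with DMαKG, 14 of 15 with a median of -0.37 (adjusted p = 0.00121, adjusted p = 0.816 with an estimated correlation), and so were markers of macrophages and monocytes, 16 of 19 with a median of -0.37 (adjusted p = 0.0228 and 0.816). The dendritic cell call ended without WT vehicle replicate 2 (median -0.09, adjusted p = 0.448) or WT DMαKG replicate 3 (-0.36 and 0.0583). The macrophage call was lost without WT vehicle replicate 2 (0.686), WT vehicle replicate 3 (0.277) or WT DMαKG replicate 3 (0.756). Markers of erythroid cells passed as lower too. Their call ended without WT vehicle replicate 2 (-0.17 and 0.435) or 3 (-0.35 and 0.0509), or WT DMαKG replicate 1 (-0.24 and 0.169) or 3 (-0.17 and 0.453). Immediate-early and AP-1 genes were higher, 25 of 29 with a median of 0.45 (adjusted p = 0.0228 and 0.816). This call ended without WT vehicle replicate 4 (median 0.096, adjusted p = 0.446), WT DMαKG replicate 1 (0.27 and 0.228) or WT DMαKG replicate 2 (0.15 and 0.382). With the replicate number as a block the list passed in the opposite direction (-0.17 and 0.0207). Replicate 4 occurs only with vehicle and replicate 1 only with DMαKG, so this fit compares the treatments directly only within replicates 2 and 3. In all 12 lists passed, 6 higher and 6 lower, and 0 with an estimated correlation; 7 passed without WT vehicle replicate 2 or 3. The immediate-early call also ended with voom quality weights (adjusted p = 0.145), where the median was still 0.45. Of the settings chosen after seeing the data, removing the length and GC trend ended the immediate-early call (0.0617), though the median was 0.47. Leaving out the 3 libraries (median -0.31, adjusted p = 0.0758) or the Y-linked covariate (-0.18 and 0.577) ended the macrophage call.

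No gene passed edgeR's test for DMαKG against vehicle in WT, the smallest adjusted p being 0.999. At an unadjusted p under 0.05 there were 352 genes, 2.73% of those tested and below the share of 0.05 expected with no change. DESeq2's Wald test called 2 and limma voom with sample quality weights 9. The groups did not overlap for 8.45% of tested genes, where chance gives 10%. The separated genes with the smallest p were Xxylt1, a xylosyltransferase gene (log2 fold change 0.58, unadjusted p = 0.000293), Dnah7a, an axonemal dynein gene (0.88), and Slc14a1, a urea transporter gene (0.68), on the higher side, and Pde3b, a phosphodiesterase gene (-0.79), Ahsa2 (-0.59) and Fam177a (-0.82) on the lower. Ahsa2 overlaps Usp34 and Fam177a overlaps Gm2436, so their values are uncertain. Ctla4, an inhibitory receptor of Tregs, stood at 758 ± 156 CPM with vehicle and 1319 ± 697 CPM with DMαKG (SD, n = 3; log2 fold change 0.80, adjusted p = 0.999). Its values with DMαKG were 1722 CPM in replicates 1 and 2 and 514 CPM in replicate 3. Tkt had a log2 fold change of 0.35 (adjusted p = 0.999), Foxp3 of 0.24, Il2ra of 0.19 and Il10 of 0.42. Leaving out each library in turn gave 0 genes each time. Without WT DMαKG replicate 3, however, 1222 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.152.

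The third comparison asked what DMαKG changed in cKO Tregs. Interferon-stimulated genes fell, 37 of 40 members being lower and 3 higher, with a median log2 fold change of -0.65 (camera adjusted p = 1.07e-10, adjusted p = 0.56 with an estimated correlation). Adjusted over the list alone, 22 were lower and 1 was higher, while over all genes 0 passed. Slfn5, a member of the interferon-inducible Schlafen family, stood at 221 ± 17.9 CPM with vehicle and 122 ± 4.2 CPM with DMαKG (SD, n = 3; log2 fold change -0.86, adjusted p = 0.125), and Slfn1, of the same family, at 207 ± 53.9 and 75.5 ± 6.45 CPM (-1.46, adjusted p = 0.125). The call of the list held without each of the 6 libraries, with medians from -0.76 to -0.51.

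Treg suppressive molecules and effector Treg genes rose in cKO with DMαKG. Of the suppressive molecules 15 of 19 were higher, with a median of 0.45 (adjusted p = 0.00117, adjusted p = 0.56 with an estimated correlation), and 4 passed adjusted over the list alone. Ctla4 stood at 701 ± 232 CPM with vehicle and 2425 ± 528 CPM with DMαKG (SD, n = 3; log2 fold change 1.79, SE 0.41, adjusted p = 0.132), higher in 3 of 3 libraries but short of the threshold over all genes. Of the effector Treg genes 19 of 26 were higher, with a median of 0.49 (adjusted p = 0.000229, adjusted p = 0.56 with an estimated correlation), and 6 passed adjusted over the list alone; Itgae, the integrin CD103 gene, which overlaps Haspin, had a log2 fold change of 1.06 (adjusted p = 0.125) and Ccr8, a chemokine receptor of effector Tregs, of 1.18 (adjusted p = 0.132). The Treg core signature rose by a median of 0.14 (20 of 28 higher, adjusted p = 0.00716, adjusted p = 0.56 with an estimated correlation), with 9 members higher and 1 lower adjusted over the list alone, Tnfrsf4 among them (0.78). Resting Treg and naive T cell genes fell by a median of -0.27 (15 of 20 lower, adjusted p = 0.024, adjusted p = 0.718 with an estimated correlation); Id3, an inhibitor of E proteins, had a log2 fold change of -1.41, whereas Ccr7, a lymph node homing receptor, had one of 1.92. The call of the resting list ended without cKO vehicle replicate 3 (median -0.30, adjusted p = 0.0776), cKO DMαKG replicate 1 (-0.19 and 0.112) or cKO DMαKG replicate 3 (-0.22 and 0.067).

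Proliferation and ribosomal lists rose in the same comparison. Genes of mitosis were higher in 38 of 40 members, with a median of 0.70 (adjusted p = 3.94e-08, adjusted p = 0.766 with an estimated correlation), and genes of DNA replication and S phase in 37 of 40, with a median of 0.45 (adjusted p = 1.14e-06 and 0.766). Aurka, a mitotic kinase gene that overlaps Cstf1 and is uncertain, had a log2 fold change of 0.99 (adjusted p = 0.217) and Pcna, the replication clamp, of 0.67 (adjusted p = 0.206); 0 members of either list passed adjusted over the list alone. Without cKO vehicle replicate 2 the S phase median was 0.14 (adjusted p = 0.0947). Ribosomal protein genes were higher in 80 of 82 members, with a median of 0.36 (adjusted p = 7.46e-10, adjusted p = 0.766 with an estimated correlation), and this rested on cKO DMαKG replicate 3, without which the median was 0.05 (adjusted p = 0.248). With the length and GC trend removed the median was 0.20 (adjusted p = 8.3e-07) and with the Y-linked covariate 0.21, both chosen after seeing the data. Oxidative phosphorylation genes had a median of 0.15 (adjusted p = 0.00952 and 0.91), which was -0.02 (0.773) without cKO DMαKG replicate 3 and lost without cKO vehicle replicate 2 (0.97) or 3 (0.115). Immediate-early and AP-1 genes had a median of 0.52 (adjusted p = 0.00723 and 0.842). This call ended without cKO vehicle replicate 4 (median 0.20, adjusted p = 0.498), cKO DMαKG replicate 1 (0.41 and 0.0655) or cKO DMαKG replicate 2 (0.50 and 0.0985). Th17 genes had a median of 0.36 (adjusted p = 0.0438 and 0.56), with Ahr, the aryl hydrocarbon receptor, at 0.90 (adjusted p = 0.115). Their call was lost without cKO vehicle replicate 2 (0.107), 3 (0.0512) or 4 (0.126), or cKO DMαKG replicate 2 (0.145) or 3 (0.326).

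Markers of B cells were higher in the cKO libraries with DMαKG, 14 of 14 with a median of 0.71 (adjusted p = 0.00381, adjusted p = 0.718 with an estimated correlation). This call ended without cKO DMαKG replicate 3 (median 0.20, adjusted p = 0.248) or cKO vehicle replicate 2 (0.57 and 0.0609). Cd22 stood at 15.4 CPM with vehicle and 25.9 CPM with DMαKG. Markers of dendritic cells had a median of 0.73 (adjusted p = 0.0501), of macrophages and monocytes 0.68 (0.0504), of plasma cells 1.5 (0.0658) and of neutrophils 1.44 (0.0658), and none of these passed; the effector and suppressive lists above had medians of 0.49 and 0.45 in the same libraries. In the same libraries the Y-linked genes were low in cKO DMαKG replicates 1 and 3 and high in all 3 cKO vehicle libraries.

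No single gene passed edgeR's test for DMαKG against vehicle in cKO, the smallest adjusted p being 0.0832. At an unadjusted p under 0.05 there were 2229 genes, 17.3% of those tested, where a share of 0.05 is expected with no change. DESeq2's Wald test called 389 and limma voom with sample quality weights 449. The groups did not overlap for 21.1% of tested genes, where chance gives 10%. Gm3512, a predicted gene on chromosome 14, stood at 30.6 and 79.3 CPM (log2 fold change 1.37, adjusted p = 0.0832), Haspin, a histone kinase gene that lies inside Itgae and is therefore uncertain, at 22.3 and 57.4 CPM (1.36, adjusted p = 0.0832), and Fam177a at 52.9 and 18.5 CPM (-1.52, adjusted p = 0.0834). Eef1aknmt, a methyltransferase of elongation factor 1A, had a log2 fold change of -0.73 and Ncoa7 of -0.56. Nfe2l2, which encodes the oxidative stress regulator NRF2, stood at 32.4 and 14.8 CPM (-1.13, adjusted p = 0.115), and Tet2, a 2-oxoglutarate-dependent DNA demethylase, at 80.1 and 122 CPM (0.61, adjusted p = 0.144); neither passed. Tkt had a log2 fold change of -0.02 (SE 0.21), near 0 and of either sign across the alternatives, and Foxp3 of 0.12. The count was 137 without WT DMαKG replicate 3, 10 without cKO vehicle replicate 2, 1 without WT vehicle replicate 3 or 4, and 0 without each other library. It was 15 without the 3 libraries that lay together at one end of the first component and 0 with the Y-linked level as a covariate, alternatives chosen after seeing the data. With that covariate 663 genes had an unadjusted p under 0.05, against 2229 without it. The Y-linked level and the treatment nearly coincide in the cKO libraries, so the excess cannot be assigned to DMαKG or to the Y-linked difference. Of the lists, 12 passed, 10 higher and 2 lower, and 0 with an estimated correlation. Calls also ended with voom quality weights for Th17 (median 0.31, adjusted p = 0.336), immediate-early (0.28 and 0.675) and B cell genes (0.22 and 0.508), and without a low-count filter for Th17 genes (0.30 and 0.162). Of the settings chosen after seeing the data, leaving out the 3 libraries ended resting Treg (median -0.25, adjusted p = 0.0805), Th17 (0.37 and 0.0943) and immediate-early genes (0.21 and 0.0805). The Y-linked covariate ended oxidative phosphorylation (0.086 and 0.0690), resting Treg (-0.22 and 0.120) and immediate-early genes (0.25 and 0.0870), and removing the length and GC trend oxidative phosphorylation (0.015 and 0.7) and Th17 genes (0.34 and 0.0608).

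The fourth comparison asked what the loss of transketolase changed in mice given DMαKG. Kit, the receptor of stem cell factor, rose from 7.00 ± 0.76 CPM in WT to 19.4 ± 0.57 CPM in cKO (SD, n = 3; log2 fold change 1.47, SE 0.18, adjusted p = 0.013). Il1r2, the decoy receptor of interleukin-1, rose from 39.9 ± 17.7 to 148 ± 36.2 CPM (1.89, adjusted p = 0.0415), and Cd80, a costimulatory ligand, from 3.81 ± 0.55 to 8.38 ± 1.23 CPM (1.14, adjusted p = 0.0468). Fn1 (fibronectin, log2 fold change 2.39) and Hspg2 (perlecan, 2.59), genes of extracellular matrix proteins, rose too, Fn1 from 1.13 to 5.95 CPM and Hspg2 from 0.486 to 2.96 CPM. Ncf1 and Phlda3 rose as they did with vehicle (0.90 and 1.53). Tkt, Nrn1 (-1.07) and Slfn5 (-0.92, adjusted p = 0.0468) fell.

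These were among the 24 genes that passed in cKO against WT with DMαKG, 21 higher and 3 lower. Kit lies on chromosome 5 (75574987 to 75656722), Il1r2 on chromosome 1 (40084692 to 40125230) and Slfn5 on chromosome 11 (82951349 to 82964850). Others that rose were Cpe, carboxypeptidase E (1.29), Ifitm2, an interferon-induced membrane protein gene (1.22), Pls3, an actin-bundling plastin gene (1.93), Penk, which encodes proenkephalin (0.98), and Kynu, kynureninase (2.64). Hspg2, Penk and Kynu fall outside the rule for named genes and were chosen after their values were seen. Haspin (1.19) and Smarcd3 (1.93) rose as well, and are uncertain because they overlap Itgae and Chpf2. Foxp3 had a log2 fold change of -0.05, Il2ra of -0.12, Ikzf2 of 0.08, Il10 of -0.33 and Tnfrsf18 of 0.46, and Ctla4 had 0.88 (adjusted p = 0.478); none passed. At an unadjusted p under 0.05 there were 1348 genes, 10.4% of those tested, where a share of 0.05 is expected with no change. DESeq2's Wald test called 143 and limma voom with sample quality weights 255. The groups did not overlap for 15.0% of tested genes, where chance gives 10%.

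Ribosomal protein genes were higher in cKO in 82 of 82 members, with a median of 0.31 (camera adjusted p = 5.39e-10, adjusted p = 0.697 with an estimated correlation), and oxidative phosphorylation genes in 70 of 72, with a median of 0.20 (adjusted p = 1.45e-05 and 0.788). Without cKO DMαKG replicate 3 these medians were 0.01 (0.811) and 0.03 (0.589). Glutamine and glutamate metabolism genes rose, 17 of 22 being higher with a median of 0.20 (adjusted p = 0.00513, adjusted p = 0.492 with an estimated correlation); adjusted over the list alone 2 passed, Got1, the cytosolic aspartate aminotransferase (41 and 72.8 CPM, log2 fold change 0.83), and Gls2, a glutaminase (1.91), which overlaps Spryd4 and is uncertain. Glycolysis genes rose by a median of 0.12 (adjusted p = 0.027 and 0.492), with Eno2 at 1.15 (adjusted p = 0.0872). The glycolysis call ended, with larger medians, without WT DMαKG replicate 1 (0.17, adjusted p = 0.0609), cKO DMαKG replicate 1 (0.14 and 0.129) or cKO DMαKG replicate 2 (0.13 and 0.0526). Interferon-stimulated genes fell, 29 of 40 being lower with a median of -0.37 (adjusted p = 0.00214, adjusted p = 0.708 with an estimated correlation), Slfn5 over all genes and 4 members adjusted over the list alone, with 1 higher; without WT DMαKG replicate 3 the median was -0.08 (0.417), and without cKO DMαKG replicate 2 it was -0.20 (0.0735). Resting Treg and naive T cell genes fell by a median of -0.22 (15 of 20 lower, adjusted p = 0.00513 and 0.492), 3 adjusted over the list alone, among them Ccr9, a gut homing receptor (-0.98), and Itgb3, integrin β3 (-0.75).

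Genes of mitosis had a median of 0.30 (38 of 40 higher, adjusted p = 0.0312, adjusted p = 0.867 with an estimated correlation) and those of S phase 0.21 (36 of 40 higher, adjusted p = 0.0312 and 0.861). Without cKO DMαKG replicate 1 these were -0.07 (0.855) and 0.01 (0.928), and without WT DMαKG replicate 3 0.08 (0.835) and 0.06 (0.795). The mitosis call also ended without WT DMαKG replicate 1 (adjusted p = 0.0767), with the median still at 0.30. Markers of B cells were higher, 14 of 14 with a median of 0.35 (adjusted p = 0.0286 and 0.697), and so were markers of plasma cells, 4 of 5 with a median of 2.06 (adjusted p = 0.0329 and 0.492). Without cKO DMαKG replicate 3 these medians were -0.23 (0.771) and 0.40 (0.153). The B cell call also ended without WT DMαKG replicate 3 (median 0.22, adjusted p = 0.184). The plasma cell call ended without WT DMαKG replicate 1 (2.07 and 0.0897), WT DMαKG replicate 3 (1.81 and 0.07) or cKO DMαKG replicate 2 (2.18 and 0.0545). Markers of erythroid cells passed as lower, a call that ended without WT DMαKG replicate 2 (-0.48 and 0.145) or cKO DMαKG replicate 2 (-0.42 and 0.216). In all 14 lists passed, 11 higher and 3 lower, and 0 with an estimated correlation. The list count was 7 without WT DMαKG replicate 3 and 9 without cKO DMαKG replicate 2. Calls also ended with voom quality weights for ribosomal (median 0.023, adjusted p = 0.725), oxidative phosphorylation (0.083 and 0.0786), B cell (-0.22 and 0.881) and plasma cell genes (0.52 and 0.105), and without a low-count filter for mitosis (0.31 and 0.0568), S phase (0.22 and 0.0568) and plasma cell genes (1.39 and 0.131). Of the settings chosen after seeing the data, leaving out the 3 libraries ended interferon-stimulated (median -0.08, adjusted p = 0.279), S phase (0.056 and 0.738), mitosis (0.073 and 0.771), B cell (0.22 and 0.187) and plasma cell genes (1.81 and 0.102). The Y-linked covariate ended S phase (0.17 and 0.102), mitosis (0.20 and 0.102), B cell (0.25 and 0.118) and plasma cell genes (1.38 and 0.0588), and removing the length and GC trend oxidative phosphorylation (0.058 and 0.0835). The gene count was 10 without WT vehicle replicate 3, 5 without WT vehicle replicate 4, and 2 without WT vehicle replicate 2 or cKO vehicle replicate 3. It was 3 without WT DMαKG replicate 1, cKO DMαKG replicate 1 or cKO DMαKG replicate 2, and 1, Tkt, without WT DMαKG replicate 2 or 3. Fitted on the 6 libraries compared alone, 3 genes passed, and with the replicate number as a block 0 passed. With the Y-linked level as a covariate 4 genes passed, and without the 3 libraries that lay together on the first component 1 gene passed; both were chosen after seeing the data.

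**Figure D4:**
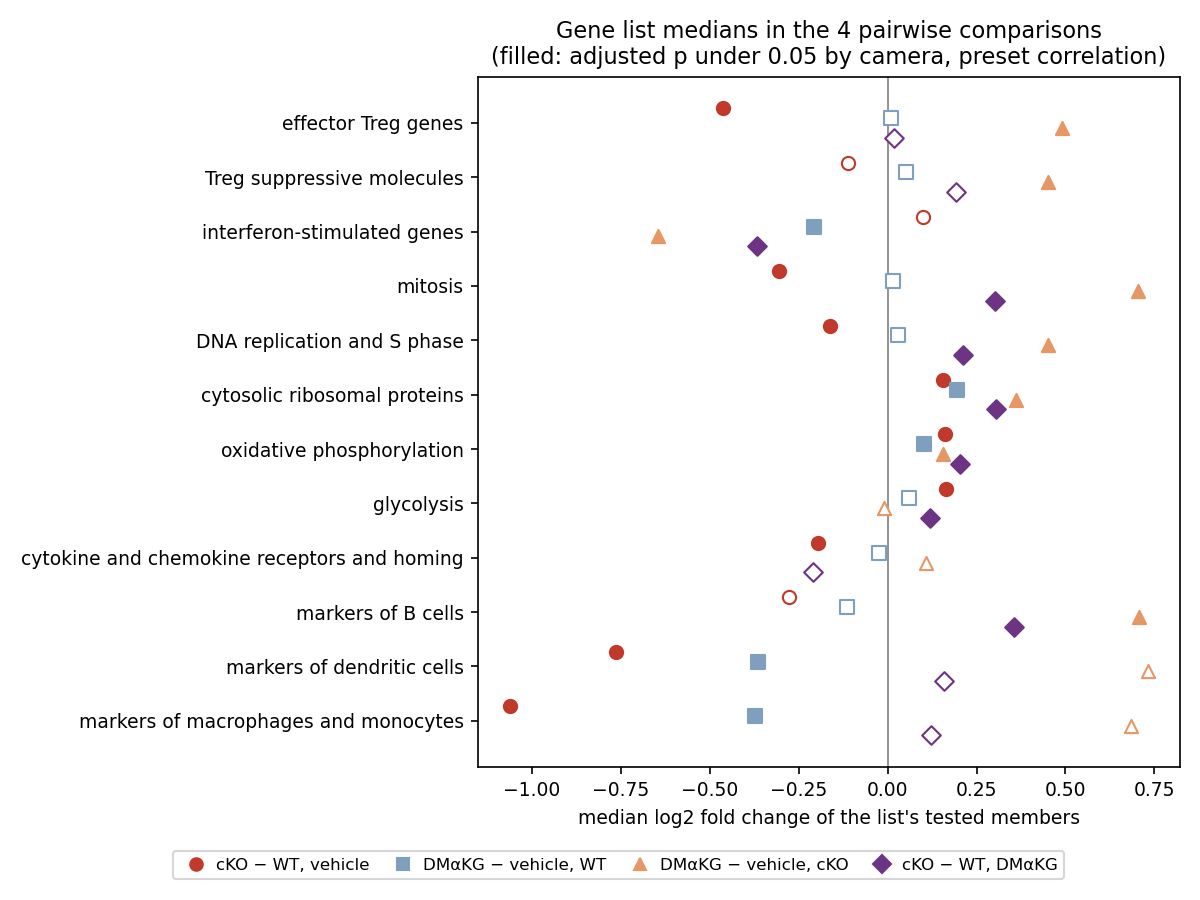
Median log2 fold change (horizontal axis) of 12 gene lists in the 4 pairwise comparisons, 1 marker shape per comparison; filled markers have an adjusted p under 0.05 by camera with the preset correlation. The median of interferon-stimulated genes is -0.65 for DMαKG against vehicle in cKO, and that of mitosis genes is -0.31 for cKO against WT with vehicle and 0.70 for DMαKG against vehicle in cKO.

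The interaction asked whether DMαKG acted differently in cKO and WT. No gene passed edgeR's test, the smallest adjusted p being 0.955. At an unadjusted p under 0.05 there were 470 genes, 3.64% of those tested and below the share of 0.05 expected with no change. DESeq2's Wald test called 1 and limma voom with sample quality weights 1. The smallest p belonged to Ncoa7, whose DMαKG effect differed by -0.79 on the log2 scale (SE 0.14, unadjusted p = 8.86e-05), followed by Haspin (1.28) and Gm3512 (1.21). Of the lists 16 passed camera's test, 12 higher and 4 lower, and 0 with an estimated correlation. Genes of mitosis had a median difference of 0.62 (40 of 40 higher, adjusted p = 2.72e-09, adjusted p = 0.526 with an estimated correlation), effector Treg genes of 0.64 (22 of 26 higher, adjusted p = 3.38e-06 and 0.355) and interferon-stimulated genes of -0.39 (35 of 40 lower, adjusted p = 6.17e-07 and 0.506).

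The genotype effect with DMαKG was compared with that with vehicle, 2 contrasts that share no libraries. Across the 12903 tested genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.267 and a Spearman rho of 0.221, against a mean r of 0.0133 (SD 0.0355) in 20 simulations of unchanged groups. On group means of log2 CPM this r was 0.236, and 14 of 100 regroupings of the real libraries gave one as large (SD over regroupings 0.0894). Of the 8 genes called with vehicle 7 had the same sign with DMαKG, and the median ratio of the DMαKG fold to the vehicle fold was 71.6%. These 8, which include the deleted gene Tkt, were chosen by their vehicle folds, and such a choice tends to inflate them. The ratio therefore does not show that DMαKG reduced the genotype effect. Ncf1 and Phlda3 were called higher in both, where 0.00488 shared genes would be expected from independent lists, and Tkt and Nrn1 lower in both, where 0.00116 would be expected. Both contrasts use the same estimate of each gene's spread over all libraries, so the lists are not fully independent and these expectations may be too low. The DMαKG effects in cKO and WT had an r of 0.281 and a rho of 0.362 across genes. This r was 0.0389 without WT DMαKG replicate 2, 0.0922 without WT vehicle replicate 4 and 0.165 without WT DMαKG replicate 1.

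Whether DMαKG in cKO turned back the genotype effect was asked last. Of the 8 genes called with vehicle, 6 had the opposite sign in DMαKG against vehicle in cKO (75.0%, exact 95% Clopper-Pearson interval 34.9% to 96.8%), and 0 of them were called there by edgeR. The interval treats the 8 genes as independent, though they were measured in the same libraries, so it does not measure the spread between mice. Leaving out each library in turn gave shares from 50% to 100% of the genes then called, which were 1 to 5 genes. Both contrasts contain the cKO vehicle libraries with opposite sign, which by itself gives opposite folds. Across genes r was -0.331, whereas unchanged groups simulated with the same shared libraries gave -0.491 (SD 0.0261, 20 simulations). The covariance was -0.0669 against a simulated -0.0528 (SD 0.0037), a difference of -0.0141. Among genes with an unadjusted p under 0.05 with vehicle, 67.8% had the opposite sign, against 89.6% in the simulations. By r and by this share, unchanged groups that share these libraries gave more opposite movement than was observed, and by the covariance they gave less. These measures thus disagree and do not decide. Of 100 regroupings of the real libraries 81 gave as large a negative r on group means of log2 CPM. The shared group of 3 could not be split into parts of at least 2 libraries.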

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

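The splits of the samples were planned; the tests of a single library for interferon-stimulated and mitosis genes and of length bias as the whole cause for ribosomal genes were chosen after the result was seen.

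In 16 gene lists the DMαKG effect differed between cKO and WT by camera's test of the interaction, though in 0 with an estimated correlation, where their adjusted p ran from 0.2 to 0.94. The median difference was 0.62 for mitosis, 0.43 for DNA replication and S phase, 0.64 for effector Treg genes, 0.75 for Th17 genes, 0.42 for Treg suppressive molecules, 0.17 for glutamine and glutamate metabolism and 0.15 for cytosolic ribosomal proteins. It was -0.39 for interferon-stimulated genes, -0.33 for resting Treg and naive T cell genes, -0.16 for MYC targets and ribosome biogenesis and -0.33 for markers of conventional CD4 T cells. For markers of other cells it was 1.22 for dendritic cells, 1.14 for macrophages and monocytes, 0.75 for B cells, 2.09 for plasma cells and 2.15 for neutrophils. Leaving out 1 library ended camera's call for MYC targets (adjusted p = 0.0753 and 0.0855 without WT or cKO vehicle replicate 4), S phase (0.098) and plasma cells (0.0821) without cKO vehicle replicate 2, and macrophages without cKO DMαKG replicate 3 (0.0737). For neutrophils it ended without WT vehicle replicate 4 (0.0753), WT DMαKG replicate 1 (0.0894) or cKO DMαKG replicate 3 (0.133). For glutamine metabolism it ended without WT vehicle replicate 2 or 4, cKO vehicle replicate 2 or 4, WT DMαKG replicate 1 or 3, or cKO DMαKG replicate 1 or 2 (0.0599 to 0.183). For ribosomal proteins it ended without WT vehicle replicate 2, cKO vehicle replicate 2 or 3, or WT DMαKG replicate 2 or 3 (0.100 to 0.838). Without cKO DMαKG replicate 3 ribosomal proteins passed in the opposite direction, with a median of -0.14 (adjusted p = 4.21e-06). Calls also ended with voom quality weights for glutamine metabolism (median 0.15, adjusted p = 0.0703), B cells (0.38 and 0.203) and macrophages (0.51 and 0.224), and without a low-count filter for glutamine metabolism (0.18 and 0.118), ribosomal proteins (0.16 and 0.111) and plasma cells (1.52 and 0.110). Of the settings chosen after seeing the data, leaving out 3 libraries ended glutamine metabolism (0.18 and 0.136), MYC targets (-0.078 and 0.337) and plasma cells (1.7 and 0.0517), the Y-linked covariate macrophages (0.22 and 0.294), and removal of the length and GC trend ribosomal proteins (0.071 and 0.142).

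The real grouping gave 16 interaction lists and the highest of the other regroupings 19, with 2 of 40 reaching at least 16, so chance was not excluded. For genes the real count was 0 and the highest other 2, with all 40 at or above the real count.

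Interferon-stimulated genes were lower with DMαKG in cKO by a median log2 fold change of -0.65. With the Y-linked covariate the median was -0.39 (camera adjusted p = 1.61e-10, preset correlation). By the rule set in advance this counts against the sex of the mice as the cause. In cKO, however, the Y-linked level was high in every vehicle library and low in DMαKG replicates 1 and 3. The covariate and DMαKG are thus hard to separate, and this test cannot decide. With the preset correlation 5 of 10 splits of these libraries, the real one included, gave at least the real count of 12 list calls. The tables argue against transcript length or GC content (-0.60 with the trend removed) and against a single library (-0.51 at the nearest to 0, without cKO vehicle replicate 3). An effect of DMαKG itself stays open as a hypothesis that may account for it, and the estimated-correlation test did not pass. Differences between the groups in litter or handling were not tested.

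Mitosis genes were lower in cKO with vehicle by a median of -0.31. With the Y-linked covariate this was -0.25 and with the length and GC trend removed -0.33, which argue against both as the whole cause. Without cKO vehicle replicate 2 it was 0.021 (adjusted p = 0.498), so a single library is a candidate explanation that the values fit. An effect of the genotype stays open.

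Ribosomal protein genes were higher with DMαKG in cKO by a median of 0.36, and by 0.21 with the Y-linked covariate. Without cKO DMαKG replicate 3 the median was 0.048 (adjusted p = 0.248), so a single library may account for it. Genes nearest in length, GC content and expression had a median of 0.16, and draws from them medians of 0.16 to 0.25, below the list's 0.36. Their median length was 1271 against 677 for the list, so the match on length was incomplete. By the rule set in advance, a matched median under 0.18 with the list above the draws counts against length or GC content. Both conditions were met. The bound of 0.18 lay inside the range of the draws, a check that was not part of that rule. Because the match on length was incomplete, the draws cannot decide on length or GC content as the whole cause or as part of it. With its length and GC trend removed the list's median was 0.20 (camera adjusted p = 8.3e-07).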

How the results depend on the processing

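Among alternatives planned in advance, the results below moved; a Y-linked covariate, the removal of a length and GC trend and leaving out 3 libraries were chosen after seeing the data. Gene counts are given for cKO against WT with vehicle (8), DMαKG in WT (0), DMαKG in cKO (0), cKO against WT with DMαKG (24) and the interaction (0). DESeq2's Wald test called 100, 2, 389, 143 and 1, and limma voom with quality weights 263, 9, 449, 255 and 1. With DESeq2 size factors 3 genes passed in the first comparison, and without a low-count filter 4 passed for DMαKG in cKO. With only the groups compared in the fit, 0 passed in the first (1109 at an unadjusted p under 0.05), 4 for DMαKG in cKO and 3 in the fourth; fewer libraries then estimate the spread. At an adjusted p below 0.01 there was 1 in the first and 1 in the fourth. The Y-linked covariate left 3 and 4 there, and leaving out the 3 libraries left 3 and 1, with 15 for DMαKG in cKO.

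With the replicate number as a block 1 gene passed in the first comparison and 0 in the fourth by edgeR (1205 at an unadjusted p under 0.05). Same-numbered libraries deviated from their group means with correlations from -0.281 to 0.466, the latter between WT and cKO vehicle replicate 4. This range does not show a pairing by number and does not exclude one. Under the block, immediate-early and AP-1 genes had a median of -0.17 for DMαKG in WT, past the threshold in the opposite direction (camera adjusted p = 0.0207). In the DMαKG contrasts not every replicate number occurs under both treatments, so the block leaves fewer libraries for a direct comparison. The block ended camera's call for interferon-stimulated genes (-0.047, adjusted p = 0.406) and erythroid markers (0.329) for DMαKG in WT, immediate-early genes for DMαKG in cKO (0.619), erythroid markers in the first (0.0994) and the fourth comparison (0.0693) and ribosomal protein genes in the interaction (0.0822), and no other list call.

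With an estimated correlation 0 lists passed in each of the 5 contrasts. Leaving out the 3 libraries gave 11 lists in the first and 7 in the fourth, and the Y-linked covariate gave 9 in the fourth. With that covariate the genotype effects had an r of 0.167 and the DMαKG effects 0.0709, and the opposite-sign share was 100% there and 100% without the 3 libraries. With voom quality weights the median of B cell markers in the fourth comparison was -0.22 and that of ribosomal protein genes in the interaction -0.044, which was -0.031 with the covariate. The cause was not tested.

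Leaving out 1 library gave 1 to 5 genes in the first comparison, 0 to 0 for DMαKG in WT, 0 to 137 in cKO, 1 to 33 in the fourth and 0 to 0 in the interaction. It gave 12 to 22, 7 to 13, 8 to 14, 7 to 15 and 14 to 23 lists, r from 0.248 to 0.372 for genotype and 0.0389 to 0.393 for DMαKG, and an opposite-sign share of 50% to 100%. List medians turned without cKO vehicle replicate 2 (S phase 0.081, mitosis 0.021) or 4 (oxidative phosphorylation -0.0090) in the first comparison, where the other ends of their ranges were -0.58, -1.12 and 0.26. For DMαKG in WT they turned without WT vehicle replicate 4 (interferon-stimulated 0.0072) or WT DMαKG replicate 3 (macrophages 0.0072), and immediate-early genes had 0.096 with camera's direction down without WT vehicle replicate 4; the other ends were -0.38, -0.998 and 0.81. Without cKO DMαKG replicate 3 they turned for oxidative phosphorylation in cKO (-0.017), B cell markers in the fourth comparison (-0.23) and ribosomal protein genes in the interaction (-0.14), with other ends of 0.32, 0.72 and 0.34. The ribosomal value passed in the opposite direction (adjusted p = 4.21e-06), and the values for oxidative phosphorylation (0.773) and B cell markers (0.771) did not pass. Mitosis in the fourth comparison turned without cKO DMαKG replicate 1 (-0.065, other end 0.56). Of 1089 list values 817 kept their direction and call, 258 lost the call and 14 turned. Of 8330 values of named genes 7889 kept their side of the threshold, 327 lost and 114 gained the call; 45 values that were not called changed sign, and 0 called values did. At these depths and 3 mice per group a change of 1.5-fold was recovered for 22.0% of simulated genes with a mean of at least 5 CPM. That run made 153 calls, so its adjusted threshold was easier to pass than in the real comparisons by edgeR.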

Other observations

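Comparisons averaged over the other factor, the relation of the first principal component to Y-linked genes and the test of distance from Tkt as the cause of most calls were chosen after the result was seen, and so were the genes named here.

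Averaged over both treatments, 130 genes differed between cKO and WT by edgeR, 98 higher and 32 lower. Among the higher were Fn1, fibronectin (log2 fold change 2.20, adjusted p = 0.00244), Lama5, a laminin chain (1.74, adjusted p = 0.00598), and Hspg2, perlecan (2.10, adjusted p = 0.00711). Eno2 (1.14), Ldhb (0.50), Il1r2 (1.36), Cd80 (0.80), Penk (0.73) and Plagl1 (0.69) were higher as well. Among the lower were the chemokine receptor genes Cxcr6 at -1.14, Ccr2 at -1.75 (adjusted p = 0.0152) and Ccr9 at -0.87, and lower as well were Nkg7, a cytotoxic granule gene (-0.78), and F13a1, a coagulation factor gene (-2.11). Cxcr6 overlaps Fyco1 and is uncertain. Cybb, the membrane subunit of the NADPH oxidase, was lower (-0.87, adjusted p = 0.0391) whereas Ncf1, a cytosolic subunit, was higher (1.19, adjusted p = 0.000188). By camera with the preset correlation 10 lists passed. Higher were ribosomal proteins (median 0.22), oxidative phosphorylation (0.19), glutamine metabolism (0.18), the Treg core signature (0.17), p53 targets (0.15) and glycolysis (0.12), and lower were erythroid markers (-0.58), Th2 genes (-0.56), effector Treg genes (-0.24) and homing receptors (-0.19). The effector Treg median was -0.46 with vehicle and 0.017 with DMαKG, and each other list that passed here had the same sign under both treatments. Markers of macrophages and monocytes had a median of -0.43 (adjusted p = 0.0529) and those of dendritic cells -0.21 (0.0938) in the same comparison, and neither passed. Their medians were -1.06 and -0.76 with vehicle, and 0.12 and 0.16 with DMαKG. An estimated correlation was not run on the averaged lists. The count of genes was 108 with the Y-linked covariate, and leaving out 1 library gave 52 (without WT vehicle replicate 2) to 164 (without cKO DMαKG replicate 3). DESeq2's Wald test called 398 and limma voom with sample quality weights 1067.

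Averaged over both genotypes, 1 gene differed between DMαKG and vehicle by edgeR, H1f3, a linker histone gene (2.42, adjusted p = 0.0200). There were 2051 at an unadjusted p under 0.05 (15.9% of those tested), 331 by DESeq2 and 1563 by limma voom with sample quality weights. With the length and GC trend removed 0 genes passed by edgeR. Interferon-stimulated genes had a median of -0.44 and ribosomal protein genes of 0.27. By camera 9 lists passed. Leaving out 1 library gave 0 (without WT vehicle replicate 2, for example) to 619 genes (without WT DMαKG replicate 3).

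For the averaged genotype comparison the real grouping gave 130 genes and the highest other 1, with 1 of 50 groupings reaching it, a share under 0.05. This comparison was chosen after the single genotype comparisons were seen, so the share is not a planned test and does not by itself exclude chance. For the averaged DMαKG comparison the real count was 1 and the highest other 229, with 3 of 50 at or above the real one, so chance was not excluded. What the grouping with 229 genes separates was not examined, and the real grouping gave 619 genes without WT DMαKG replicate 3. For the pairwise comparisons the 10 splits are too few for a share under 0.05. With vehicle the genotype gave 8 genes against 0 at the highest other and 17 lists against 18, and with DMαKG 24 genes against 0 and 14 lists against 12. DMαKG gave 0 genes against 0 and 12 lists against 15 in WT, and 0 genes against 2 and 12 lists against 16 in cKO. As many were reached by 1, 2, 1, 1, 10, 4, 10 and 5 of the 10 splits in that order. On group means of log2 CPM, a simpler measure than the fitted folds, regrouping gave a genotype r as large in 14 of 100 draws (0.236 against 0.411), a DMαKG r in 19 (0.295 against 0.594) and a reversal r in 81 (-0.352 against -0.823), so chance was not excluded for these.

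The first principal component went with the Y-linked level over the 12 libraries (Pearson r = -0.655, permutation p = 0.0219; Spearman rho = -0.818, permutation p = 0.00194; 1 relation tested). Without WT vehicle replicate 3 and cKO DMαKG replicate 1 r was -0.830, and of deviations within groups -0.549. A difference in sex between the mice could be part of this structure, but leaving out those 2 libraries of low Y-linked level did not weaken r. WT vehicle replicate 3, with the lowest Y-linked level (-1.56 log2 CPM), lay at 2.77 on the component. WT vehicle replicate 2, with a high level (5.82), lay near it at -0.10. The presence or absence of Y-linked transcripts thus does not by itself account for the relation, and other differences between the mice stay open. WT DMαKG replicate 2 had a Y-linked level between those of the other libraries, so it may be a mixture of cells from mice of both sexes, which was not tested. Whether the 3 libraries at one end of the component shared a batch is not given in the sources used here.

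Variants of another strain near the deleted locus could also change genes on chromosome 14. Of 128 genes called in the averaged comparison with a position, Tkt left out, 4 lay within 20 Mb of Tkt (Prxl2a, Cacna1d, Tmem273 and Dlg5, of which Cacna1d overlaps Dcp1a and Chdh and is uncertain), where 1.60 were expected (one-sided Fisher's exact p = 0.0768). By the rule set in advance, a count under 5 with a Fisher p above the threshold counts against linked variants. Both conditions were met. The exact 95% interval of the count, 1.09 to 10.2, includes the bound of 5, a check that was not part of that rule. Whether linked variants changed these 4 genes thus stays undecided. The other 124 lay farther away or on other chromosomes, which argues against linked variants as the cause of most calls.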
